A study of Mus musculus with 12 samples.

How the data were processed

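Single-cell RNA sequencing was used to count transcripts in cells isolated from the livers of male C57BL6/JBomTac mice. Per the labels, 6 libraries came from mice given a Western diet with fructose at 42 g per litre of drinking water for 52 weeks, which the labels describe as advanced NASH, and 6 libraries came from mice given chow for 52 weeks. NASH (non-alcoholic steatohepatitis, also called MASH) is fatty liver disease with inflammation and scarring. Mice were fasted overnight. Cells were released by enzymatic digestion, cells carrying ASGR1 (a hepatocyte surface receptor) or CD31 (an endothelial surface protein) were partly removed with fluorescent antibodies, and unstained live singlets were collected by FACS, per the labels' protocols. Libraries were lettered A to F in each group. The labels place A to D on isolation day 1 and E and F on isolation day 2 in both groups. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these libraries.

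Per the labels, libraries were made with the 10x Genomics 3' v2 protocol, which tags each transcript with a unique molecular identifier (UMI). Whether this held on day 2 is uncertain, since a day 1 and a day 2 library shared 0 to 2 barcodes per pair. The deposited files hold raw UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mm10 genome were used. Per the file headers, the matrices were written by Cell Ranger 3.0.2 on day 1, with 31053 genes, and by Cell Ranger 4.0.0 on day 2, with 32285 genes. The steps between these versions were not given in the sources used here. Genes were joined by identifier, and the 30406 genes found in all 12 libraries were used. They held at least 99.5% of each library's UMIs, and all 30406 matched the GENCODE M21 annotation (GRCm38, the assembly called mm10), which gave the gene coordinates.

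Everything that follows was computed from those counts. Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which left 42549 of 47905. In each library, the cells with the highest Scrublet doublet scores were then removed, in the number given by a rate of 0.8% per 1000 barcodes (1643 cells), and 40906 cells were retained. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1 gave the clusters, and mixed clusters were divided again at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15). Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 detected markers, a marker score of at least 0.5, and at least 1 marker of its class, and no fewer than of any other class, among the cluster's 10 genes with the largest fold. Ties went to the class with the higher marker score. They named 6 clusters with 1010 cells: 838 of 14850 endothelial-like, 116 of 8250 mononuclear phagocyte-like and 56 of 88 basophil and mast-like cells. The score minimum, the detection minimums (25% of cells for leading genes, 10% for markers) and the use of the 10 leading genes were set after the clusters were seen, because a score alone had named a cluster against its leading genes. Names are written "X-like", since they rest on markers. Of 65 clusters, 58 were named, into 17 classes, and 7 with 400 cells were left unnamed. These made up 1.19% ± 0.57 (SD, n = 6) of retained cells with the Western diet and 0.575% ± 0.73 (SD, n = 6) with chow.

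Counts were summed per library and class. A class entered a gene test with the libraries that held at least 10 of its cells, if at least 3 libraries per group remained. The tests, samples, covariates, gene lists and the alternatives below, apart from the 3 named as added, were fixed before the data were examined. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15) and isolation day as an additive term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Adjusted p-values of genes below are from this test unless another tool is named. Standard errors (SE) of log2 fold changes were computed as the absolute fold change divided by the square root of the F statistic. Levels are CPM, the summed counts of a class scaled to the library's total in that class. The diet effect by isolation day was tested as an interaction term in the same model. Shares of cells were tested with a two-sided exact permutation test within isolation day, with 420 arrangements and a smallest possible p of 0.00476, adjusted over the 17 classes.

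Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a class, with the correlation also estimated from the data and with fry beside it. Of 37 calls at the preset correlation in the classes, 6 held with an estimated correlation: MHC class II and interferon response in stellate-like cells, Kupffer identity in mononuclear phagocyte-like cells, MHC class II and capillary genes in endothelial-like cells, and chemokines and cytokines in cholangiocyte-like cells. In the Kupffer-led cluster 0 of 7 such calls held (adjusted p = 0.208 to 0.433). Counts of list members are given over all genes tested and "adjusted over the list alone". Biology lists covered matrix, matrix crosslinking, contractile, retinoid, secreted-signal, receptor and transcription factor genes of stellate cells, TGF-beta response, chemokines and cytokines (with adhesion molecules), Kupffer identity, lipid-associated macrophage, monocyte, MHC class I and II, interferon response, sinusoidal identity, angiocrine, capillary, biliary identity, ductular reaction, T cell residency and exhaustion, T cell effector, naive T cell, cholesterol synthesis, LXR targets, fatty acid oxidation and PPAR targets, and ER stress. Technical lists covered dissociation stress, cell cycle, mitochondrial genes, and transcripts of hepatocytes, erythroid cells, plasma cells (immunoglobulin) and neutrophils. A list with fewer than 3 measured members in a class was not tested there.

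The rule for named genes was also fixed before the data were examined. Its first part took called genes with a mean of at least 20 CPM, a difference of the same sign on both days, and no place on a technical list, leaving out ribosomal protein genes, Xist and Y-linked genes. From these it named the 8 largest positive and 8 largest negative fold changes of each main class (3 and 3 in further classes) with at least 10% of the level of the class where the gene was highest. Its second part named up to 4 called members of each biology list with the smallest p, with none of these other conditions, so low levels and genes also on a technical list occur there. The rule gave 212 names, of which 123 are reported. That subset was chosen after the values were seen. The names not reported include 7 left out in part because single libraries decided their calls: Angptl6, Icam1, Rdh10, Tgfbr3, Tmem100 and Ets1 in stellate-like cells and Id2 in cholangiocyte-like cells. Items withheld for evaluation are not reported here. List members beyond these are named to describe a count. Apoe in T cell-like cells, genes within the Kupffer-led cluster and genes of the diet by day test fell outside the rule and were chosen after their values were seen. Counts of genes in near-identical families (Mup7 and Mup12, Saa1 and Saa2, Hamp2, Cyp4a14 and AC168977.1) could be divided between copies by the authors' counting, so their values are uncertain.

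Each statistic was tested on simulated data before the reported run. For the gene, list and interaction tests, each gene was drawn independently from the real means and library sizes, with 200 genes changed. The gene tests had been run once on the real data before this, and were not altered afterwards. At a true fold of 4, edgeR recovered 100% of changed genes in stellate-like, 99% in mononuclear phagocyte-like, 98% in endothelial-like, 100% in cholangiocyte-like, 99% in T cell-like, 99% in hepatocyte-like, 95% in B cell-like and 100% in mesothelial-like cells. At a fold of 2 the shares were 83%, 89%, 82%, 93%, 93%, 83%, 51% and 71%, in the same order. False calls were 2.04% to 7.58% of calls. limma-trend recovered 15% at a fold of 2 and 62% at a fold of 4 in stellate-like cells. The interaction test recovered 43%, 79.5%, 65.5%, 81% and 73.5% of changes of fold 4 in the first 5 of these classes. In the share test, a 6-fold change of 1 class passed in 96.5% of 200 simulated sets. Of unchanged simulated lists, 2% to 4.5% had p under 0.05, with error rates for correlated genes not tested.

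Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-trend, no filter on low counts, no isolation day term, the replicate letter as a block, each day alone, each library left out, at most 20% mitochondrial UMIs, at least 1000 UMIs, no doublet removal, Leiden resolution 2, genes at 10% or more of their highest class only, libraries thinned to the smallest total of the class and, for shares, other tests and a denominator without the antibody targets. After the data were seen, 3 alternatives were added: barcodes found in several libraries of a day were removed unless 1 library held at least 80% of their UMIs, stellate-like cells were tested with at least 5 cells per library, and mononuclear phagocyte-like cells were tested in the Kupffer-led cluster alone. The 80% limit replaced a first definition after the distribution was seen. Letters A to F were checked for pairing and did not pair the libraries. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.79 to 416.9), so none was counted as deposited more than once. Figures were drawn with matplotlib 3.10.9.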

Results

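Transcripts were counted in single cells from the livers of mice kept for 52 weeks on a Western diet with fructose in the drinking water, described in the labels as advanced NASH, or on chow. The series asks which cells and genes of the diseased liver differ from the healthy liver, and its title names signalling by pericytes, the perivascular cells called hepatic stellate cells in the liver sinusoid. There were 6 libraries per diet, 4 from isolation day 1 and 2 from day 2. Western diet libraries A to F held 5887192, 8165629, 9111278, 8109715, 28639599 and 52005208 UMIs, and 2096, 3565, 2864, 2902, 2811 and 9522 cells were retained. Chow libraries A to F held 5864494, 3296010, 4107637, 3343293, 11959672 and 35667921 UMIs, and 3166, 2621, 2079, 2250, 3359 and 3671 cells were retained. Median UMIs per retained cell were 1045 to 2371.5 on day 1 and 781 to 6571 on day 2. The 40506 named cells fell into 17 classes, the most numerous being endothelial-like (14850 cells), mononuclear phagocyte-like (8250) and hepatocyte-like (5820).

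Mononuclear phagocyte-like cells, the class of Kupffer cells, monocytes and other macrophages, made up 28.5% ± 6.97 (SD, n = 6) of named cells with the Western diet and 10.5% ± 3.06 (SD, n = 6) with chow, and each Western diet library lay above each chow library. Conventional dendritic-like cells, which present antigen to T cells, made up 5.54% ± 2.34 against 2.01% ± 2.77 (SD, n = 6 per group). Endothelial-like cells made up 37.9% ± 28.9 against 52.3% ± 35.6, and stellate-like cells 2.70% ± 3.55 against 5.08% ± 2.95 (SD, n = 6 per group). Plasmacytoid dendritic-like cells, a source of interferon, made up 0.735% ± 0.59 against 0.110% ± 0.168, and hepatocyte-like cells 7.90% ± 11.4 against 17.1% ± 23.6 (SD, n = 6 per group). None of these differences passed the threshold. In the exact permutation test within day, the p-values were 0.00476 for mononuclear phagocyte-like cells (the smallest the design allows), 0.00952 for endothelial-like and for conventional dendritic-like cells, 0.0381 for plasmacytoid dendritic-like cells, 0.148 for stellate-like cells and 0.214 for hepatocyte-like cells. After adjustment over 17 classes the first 3 had p = 0.0540 in this exact test, and the others 0.162, 0.502 and 0.607. The exact test therefore called 0 of 17 classes, 4 had an unadjusted p under 0.05, and edgeR on cell numbers called 3 (conventional dendritic-like, plasmacytoid dendritic-like and hepatocyte-like). On day 1 alone the shares were 30.1% against 9.55% for mononuclear phagocyte-like cells, 55.5% against 75.1% for endothelial-like cells, 4.64% against 0.249% for conventional dendritic-like cells and 0.591% against 4.70% for stellate-like cells. On day 2 they were 25.2% against 12.3%, 2.84% against 6.69%, 7.33% against 5.54% and 6.91% against 5.83%. Shares of the 11 other classes had unadjusted p-values of 0.290 or more in the same exact test. On day 1 alone the exact p was 0.0286, the smallest possible there and not adjusted, for the 4 classes just given and for 4 more. The latter were neutrophil-like (2.16% against 0.103%, and 3.92% against 5.93% on day 2), hepatocyte-like (0.727% against 5.88%, and 22.2% against 39.4%), plasmacytoid dendritic-like (0.660% against 0.0463%, and 0.884% against 0.236%) and plasma cell-like cells (0.0510% against 0.136%, and 3.01% against 3.59%). Cells carrying ASGR1 or CD31 were partly removed before loading, which acts most directly on the shares of hepatocyte-like and endothelial-like cells. The retained cells also differed in depth between days and between the libraries of day 2, and day 2 barcodes recurred (below). Omitting 1 library changed the number of classes passing to 2 without Western diet library F, 2 without chow library E, where hepatocyte-like cells were 63.9% of named cells, and 5 without chow library F.

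**Figure D1:**
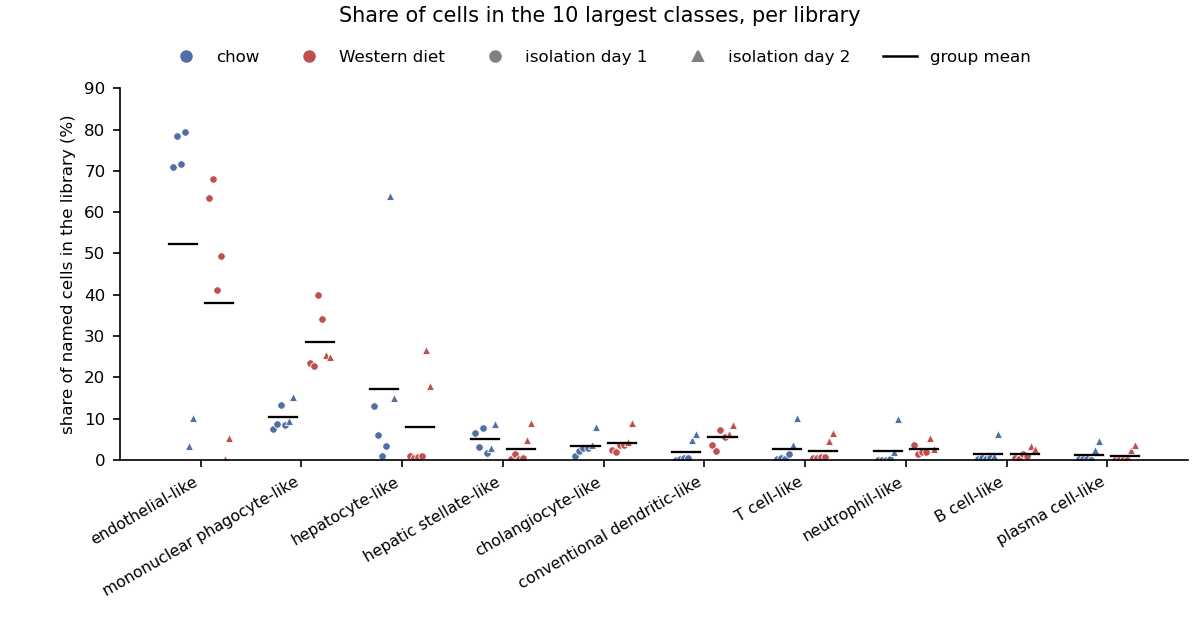
Share of named cells, in percent, in the 10 largest classes, with 1 point per library (blue chow, red Western diet, circles day 1, triangles day 2) and a black line at each group mean. Endothelial-like cells were far fewer on day 2 than on day 1 in both groups.

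Stellate-like cells of the Western diet carried more transcripts for fibrillar matrix and its processing, although these lists lost their calls with an estimated correlation. Col1a1, the main chain of type I collagen, averaged 805 CPM ± 360 (SD, n = 4) against 123 ± 46.6 (SD, n = 6), and Timp1, an inhibitor of matrix-degrading proteases, 126 ± 79.5 against 13.04 ± 21.2. The transcription factor Hand2 and the vasoactive intestinal peptide receptor Vipr1, both highest in stellate-like cells, were lower, at 430.5 ± 245 against 884.5 ± 135 CPM and 489 ± 242 against 993 ± 155 (SD, n = 4 and 6). Interferon-induced and MHC class II transcripts were higher. In all, 212 genes were higher and 118 lower of 6692 tested, in 4 Western diet and 6 chow libraries with 10 to 851 such cells and 19048 to 3722312 UMIs each. On day 1 a cluster with Aard, Ecm1 and Agtr1a among its leading genes held 85.1% of Western diet and 92.5% of chow cells. On day 2 a cluster with Gdf2, Vipr1 and Reln among its leading genes held 86.9% of Western diet cells, and one led by Ntm, Lrat and Colec10 held 90.8% of chow cells. Western diet library F gave 789 of the 859 Western diet cells in the Gdf2 cluster, which held 81.3% of Western diet cells with that library and 34.0% without it.

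Of the collagens and other matrix proteins, 17 of 36 measured members rose and 1 (Col4a2, a basement membrane collagen) fell, or 23 and 1 adjusted over the list alone (list adjusted p = 3.0e-22 by camera, adjusted p = 0.0527 with an estimated correlation). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had a log2 fold change of 2.46 ± 0.25 (SE) with an adjusted p of 1.9e-08, and its mean difference was 913 CPM on day 1 and 433 CPM on day 2. Col3a1, a fibrillar collagen, had 1.99 ± 0.23 (adjusted p = 1.9e-07), Col1a2 1.78 and Col5a2 2.03. The unlisted matrix genes Svep1 (3.02), Ccdc80 (2.55) and Dpt (2.38) and the plasminogen activator Plat (2.68) were among the largest increases under the naming rule. Dpt, Col1a1 and Col1a2 were also among the leading genes of the fibroblast-like cluster. Dpt stood at 10.2%, Plat at 12.4%, Svep1 at 15.8%, Col1a1 at 18.3% and Timp1 at 19.98% of the level of the class where each was highest. Fibroblast-like cells made up 1.21% ± 2.34 of named cells against 0.242% ± 0.205 with chow (SD, n = 6 per group), and 5.96% in Western diet library F. Of 16 fibroblast markers outside the stellate lists, 7 were measured in stellate-like cells, where 2 were higher (C3 and Dpt), 0 lower and the median log2 fold change was 0.41, a count made after the matrix result was seen. Of crosslinking and remodelling genes, 8 of 23 rose and 1, the protease Adamts1, fell (13 and 1 adjusted over the list alone, list adjusted p = 2.4e-11, adjusted p = 0.0964 with an estimated correlation). They included Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735) at 2.91 ± 0.37 and the collagen chaperone Serpinh1 at 1.21. Contractile and myofibroblast genes rose as a list with 4 of 18 called, 5 adjusted over the list alone (list adjusted p = 3.8e-06, adjusted p = 0.0964 with an estimated correlation). The 4 were the calcium-binding S100a6 (2.47, or 1.59 without Western diet library E, at 0.96% of its highest class), Crip1 (at 3.65%), the intermediate filament Vim and the tropomyosin Tpm1. ER stress genes had 6 higher and 1 lower of 21 (7 and 1 adjusted over the list alone, list adjusted p = 2.2e-05, adjusted p = 0.142 with an estimated correlation), led upward by the disulphide isomerase Pdia6 (1.14), while the stress-induced factor Atf3 (at 3.04% of its highest class) fell by 2.60.

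Stellate transcription factors fell as a list, with 3 of 33 lower and 0 higher (6 and 0 adjusted over the list alone, list adjusted p = 2.1e-04, adjusted p = 0.0964 with an estimated correlation): Hand2 (−1.01 ± 0.21, adjusted p = 0.00183), Ets1 and Klf2. Of stellate receptors, 1 of 28 rose, the oncostatin M receptor Osmr (2.20), and 3 fell, Vipr1 (−1.005), the endothelin receptor Ednrb (−1.03) and Tgfbr3 (2 and 3 adjusted over the list alone, list adjusted p = 0.347). Of secreted signals, 2 of 30 rose, Vegfa (1.60 ± 0.33), a vascular growth factor, and Gas6 (at 2.87% of its highest class), and Angptl6 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.998, median −0.08 and mean 0.04). Without Western diet library E the calls ended for Vipr1 (−0.75, adjusted p = 0.0722, range over alternatives 6.4e-05 to 0.181), Ednrb (−0.82, adjusted p = 0.0546, range 1.1e-04 to 0.673) and Vegfa (0.59, adjusted p = 0.686, range 3.1e-07 to 0.686). Among the decreases were also Egfem1 (−2.09), the membrane protein Itm2a (−1.93) and Hhip (−1.84), an inhibitor of hedgehog signalling. Retinoid and lipid storage genes had 3 of 13 higher and 0 lower, 3 and 0 adjusted over the list alone (list adjusted p = 0.138), namely the fatty acid carrier Fabp4 (2.36), Rdh10 and Lpl. Fabp4 stood at 0.45% of its level in endothelial-like cells, where it also rose (2.11). TGF-beta response genes had 0 higher and 2 lower of 20, Junb (−1.26) and Ccn1 (2 and 5 adjusted over the list alone, list adjusted p = 0.193).

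Interferon response genes rose in stellate-like cells, 10 of 31 with 0 lower (16 and 0 adjusted over the list alone, list adjusted p = 9.8e-21, adjusted p = 0.0408 with an estimated correlation), among them Irf7 (1.69), a transcription factor of the interferon response, Bst2 (1.33) and Ifi27l2a (1.52, at 2346 ± 454 against 833 ± 325 CPM). All 4 measured MHC class II genes, which present antigen, rose in both counts (list adjusted p = 2.7e-18, adjusted p = 0.0242 with an estimated correlation). H2-Ab1 (2.70) and Cd74 (2.26) stood at 0.34% and 0.36% of the level of the class where each was highest, and of 12 immune cell markers measured in stellate-like cells 8 were also higher, with a median of 2.28. Chemokine and cytokine genes had 3 of 14 higher, 4 adjusted over the list alone (list adjusted p = 0.0046, adjusted p = 0.370 with an estimated correlation, and 0.0720 without chow library E, where the range over alternatives was 2.6e-04 to 0.989). LXR targets had 1 higher, Scd1 (1.67, at 3.12% of its highest class), and 1 lower of 13 (list adjusted p = 0.195), fatty acid oxidation and PPAR target genes 2 and 2 of 22 (0.380) and MHC class I genes 0 and 1 of 12 (0.998, with median and mean −0.05 and a test direction upward). Adjusted over the list alone these were 1 and 2, 2 and 4, and 0 and 1. The cholesterol synthesis list had fewer than 3 measured members. Among technical lists, dissociation stress genes fell, 14 of 29 with 0 higher (17 adjusted over the list alone, list adjusted p = 5.1e-18, adjusted p = 0.0646 with an estimated correlation), and they include Atf3 and Junb. Mitochondrial genes were higher as a list with 0 of 13 called (list adjusted p = 0.0270, adjusted p = 0.497 with an estimated correlation). That call ended without Western diet library B (0.1796), chow library C (0.0785) or chow library D (0.0529), with a range over alternatives of 4.1e-04 to 0.497. Hepatocyte (3 higher and 2 lower of 26), immunoglobulin (0 and 1 of 3) and cell cycle transcripts (0 and 0 of 8) did not pass as lists (list adjusted p = 0.734, 0.406 and 0.818).

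The number of genes called in stellate-like cells was 112 among the 2649 testable on day 1 alone and 306 on day 2 alone. It fell to 153 without Western diet library E and 194 without chow library E, to 26 with limma-trend and to 71 without the day term. Fabp4, Vegfa, Ednrb, Vipr1, Hand2, Junb and Atf3 kept their direction but not their call in either of the last 2. Serpinh1 lost its call without the day term, and Svep1, Timp1, Plat, Dpt, Egfem1, Itm2a, Hhip, S100a6, Osmr, H2-Ab1 and Scd1 lost it with limma-trend.

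Mononuclear phagocyte-like cells of the Western diet carried fewer transcripts of resident Kupffer cells and more of those of lipid-associated macrophages, although the latter list and MHC class II lost their calls with an estimated correlation (both 0.135). Cd163, a scavenger receptor for haemoglobin, averaged 5.18 CPM ± 4.53 against 577 ± 199 with chow, and Timd4, a receptor for dying cells on resident Kupffer cells, 30.4 ± 11.5 against 305 ± 78.7 (SD, n = 6 per group). Trem2, a lipid-sensing receptor, averaged 692 ± 339 against 142 ± 54.9, Gpnmb, a glycoprotein of lipid-laden macrophages, 286 ± 163 against 32.7 ± 20.1, and the tetraspanin Cd63 984 ± 518 against 124 ± 26.9. MHC class II transcripts were higher. Of 9452 genes tested, 1822 were higher and 2013 lower, in libraries with 191 to 2343 such cells and 290370 to 17983957 UMIs. On day 1 a cluster led by Gpnmb, Trem2 and Mmp12 held 44.3% of Western diet cells, and one led by Fabp7, Folr2 and Clec4f held 85.5% of chow cells. On day 2 a cluster led by Cx3cr1, Rgs1 and Ms4a7 was the largest in both groups (26.2% and 25.2%).

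Kupffer identity genes fell in 30 of 31 measured members with 0 higher, and in 30 adjusted over the list alone (list adjusted p = 5.6e-29, adjusted p = 0.0157 with an estimated correlation). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) had a log2 fold change of −6.40 ± 0.42 (SE) with an adjusted p of 5.0e-08, and mean differences of −689 CPM on day 1 and −337 on day 2. The scavenger receptor Marco had −5.60, Timd4 −3.29 ± 0.23, the complement component C6 −3.17, the cadherin Cdh5 −2.64, the iron exporter Slc40a1 −2.26 and the nuclear receptor Nr1h3 −0.84. Lipid-associated macrophage genes had 20 higher and 1 lower (the scavenger collectin Colec12) of 31, the same counts adjusted over the list alone (list adjusted p = 6.3e-12, adjusted p = 0.135 with an estimated correlation). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) had 2.15 ± 0.22 (adjusted p = 1.5e-06), Cd63 2.80 ± 0.24, Gpnmb 2.74, the elastase Mmp12 2.44, the integrin Itgax 1.62 and the protease inhibitor Cstb 1.198. The growth factor Gdf3 (4.06) and Ms4a7 (2.20) were also among the largest increases under the naming rule. Monocyte genes had 10 higher and 2 lower of 25, also adjusted over the list alone (list adjusted p = 0.0104, adjusted p = 0.633 with an estimated correlation), with Plac8 at 1.39 and the chemokine receptor Cx3cr1 at 1.19 but the adhesion receptor Adgre4 at −1.40. On day 2 alone the direction of this list turned over (adjusted p = 0.564, range over alternatives 7.0e-07 to 0.633).

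Of 9 MHC class II genes in mononuclear phagocyte-like cells, 8 rose and 0 fell in both counts (list adjusted p = 2.5e-11, adjusted p = 0.135 with an estimated correlation), with Cd74 at 1.90, H2-Eb1 at 1.86 and H2-Aa at 1.75. Interferon response genes had 12 higher and 3 lower of 37 (14 and 4 adjusted over the list alone, list adjusted p = 0.00498, adjusted p = 0.633 with an estimated correlation). They went both ways, with the antiviral synthetase Oas1a at 2.05 and the RNA helicase Ddx60 at −1.23. On day 2 alone the list was called lower (adjusted p = 0.00384, range over alternatives 2.6e-09 to 0.633). Fatty acid oxidation and PPAR target genes had 9 higher and 2 lower of 25 in both counts (list adjusted p = 0.0428, adjusted p = 0.135 with an estimated correlation), with the oxidation enzyme Ech1 at 1.04 and the lipid droplet protein Plin2 at 0.92 but Cpt1a, which admits fatty acids to mitochondria, at −1.08. That list call ended without Western diet library A (0.0617), C (0.0509) or F (0.0697) or chow library C (0.0593), D (0.0725) or E (0.0957), with a range over alternatives of 8.6e-05 to 0.211. Chemokines and cytokines had 6 higher and 9 lower of 29 in both counts (list adjusted p = 0.576), among them the inflammatory cytokine Il6 (−3.60, at 1.12 against 11.7 CPM) and the inflammasome sensor Nlrp3 (−0.97). LXR targets had 2 higher and 5 lower of 15 in both counts (0.571), with the lipid carrier Apoe at 1.37 and the engulfment receptor Mertk at −1.16. Cholesterol synthesis (6 and 1 of 19, list adjusted p = 0.1801), MHC class I (3 and 2 of 13, 0.576) and ER stress genes (7 and 4 of 21, or 7 and 6 adjusted over the list alone, 0.576, median −0.11 and mean 0.02) did not pass. The first 2 had the same counts adjusted over the list alone.

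Among technical lists, hepatocyte transcripts fell in mononuclear phagocyte-like cells, with 21 lower and 5 higher of 39 (25 and 6 adjusted over the list alone, list adjusted p = 1.9e-05, adjusted p = 0.449 with an estimated correlation), and cell cycle genes rose, with 7 higher and 1 lower of 21 (list adjusted p = 0.0104, adjusted p = 0.563 with an estimated correlation). Dissociation stress (7 higher and 11 lower of 31, list adjusted p = 0.118), erythroid (3 and 0 of 4, 0.386), immunoglobulin (0 and 3 of 4, 0.269), neutrophil (2 and 1 of 6, 0.576) and mitochondrial genes (2 and 2 of 13, 0.898, median 0.06 and mean −0.05) did not pass. The number of genes called was 3141 on day 1 alone, 2662 on day 2 alone and 2257 without the day term, where Cx3cr1 and Plac8 lost their calls. Nr1h3 and Plin2 lost theirs on day 2 alone and Nlrp3 with thinned libraries, where 1453 genes were called.

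**Figure D2:**
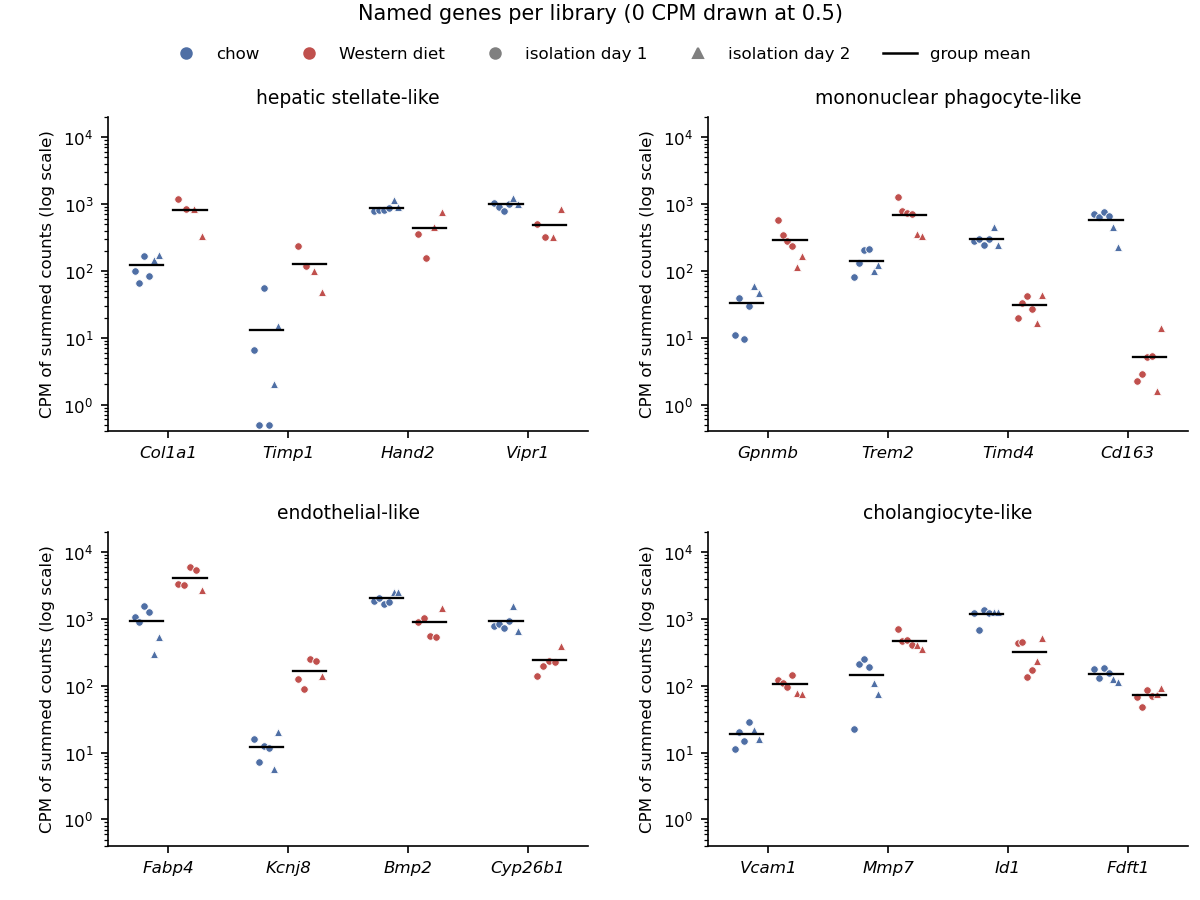
Level of 4 named genes in each of 4 classes, in CPM on a log axis, with 1 point per library (blue chow, red Western diet, circles day 1, triangles day 2), a level of 0 drawn at 0.5 and a black line at each group mean. Cd163 in mononuclear phagocyte-like cells averaged 5.18 CPM with the Western diet and 577 with chow.

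Endothelial-like cells of the Western diet carried more capillary and fewer sinusoidal transcripts, although the sinusoidal and interferon lists lost their calls with an estimated correlation (0.169 and 0.181). Fabp4, a fatty acid carrier of capillary endothelium, averaged 4113 CPM ± 1449 (SD, n = 5) against 936 ± 465 (SD, n = 6), and the potassium channel gene Kcnj8 167 ± 70.7 against 12.2 ± 5.50. Bmp2, an angiocrine signal to hepatocytes, averaged 891 ± 383 against 2069 ± 374, and Cyp26b1, which degrades retinoic acid, 238 ± 94.5 against 916 ± 330. Interferon-induced and MHC class II transcripts were higher. Of 10042 genes tested, 862 were higher and 741 lower, in 5 Western diet and 6 chow libraries with 111 to 2383 such cells and 1426824 to 3320851 UMIs. Western diet library E held too few cells. A cluster with Esm1, Fabp4 and Lyve1 among its leading genes held 57.9% of Western diet cells on day 1. One with Cyp26b1, Bmp2 and Ehd3 held 84.7% of chow cells on day 1 and 52.8% of Western diet cells on day 2. Neither was tested alone.

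Capillary genes rose in endothelial-like cells in 17 of 27 measured members with 0 lower (19 and 0 adjusted over the list alone, list adjusted p = 2.8e-16, adjusted p = 0.00518 with an estimated correlation). Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576) had a log2 fold change of 2.11 ± 0.22 (SE) with an adjusted p of 3.3e-06, and mean differences of 3267.5 CPM on day 1 and 2296 on day 2. The chemokine-binding receptor Ackr1 had 2.63, Fabp5 1.94 and the sialomucin Cd34 1.61. Sinusoidal identity genes had 8 lower and 1 higher of 23 (10 and 1 adjusted over the list alone, list adjusted p = 1.6e-04, adjusted p = 0.169 with an estimated correlation). Bmp2 (ENSMUSG00000027358, chromosome 2, 133552159 to 133562885) had −1.17 ± 0.18 (adjusted p = 1.5e-04) and the endocytic protein Ehd3 −1.17, while the hyaluronan receptor Lyve1 rose by 0.56. Angiocrine signals had 5 higher and 5 lower of 23 (5 and 6 adjusted over the list alone, list adjusted p = 0.346, median 0.07 and mean −0.15). Bmp6 (−1.81), the Wnt antagonist-family gene Dkk3 (−2.09) and the stem cell factor gene Kitl (−0.66) were among those that fell. Beyond the lists, the largest increases under the naming rule included Kcnj8 (3.68 ± 0.30, adjusted p = 1.6e-07), Armcx4 (2.57), the protease inhibitor Serpina3n (2.51), Depp1 (2.48) and the G protein regulator Rgs2 (2.32). The largest decreases under that rule included the metallothionein Mt2 (−2.001), the leukotriene synthase Ltc4s (−1.94) and Cyp26b1 (−1.90 ± 0.20).

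Interferon response genes rose in 23 of 36 members in endothelial-like cells with 0 lower (27 and 0 adjusted over the list alone, list adjusted p = 9.5e-15, adjusted p = 0.181 with an estimated correlation), with the ubiquitin-like Isg15 at 1.76, the nucleic acid sensor Zbp1 at 2.56 and Rtp4 at 1.32. All 6 measured MHC class II genes rose in both counts (list adjusted p = 4.6e-53, adjusted p = 9.2e-04 with an estimated correlation). Cd74 averaged 542 ± 177 against 65.0 ± 20.3 CPM (log2 fold change 2.92), with H2-Ab1 at 3.12 and H2-Aa at 2.84. These 3 stood at 0.91%, 1.1% and 0.77% of the level of their highest class, and 26 of 36 immune cell markers were also higher, with a median of 1.33. Chemokine and cytokine genes had 4 higher and 2 lower of 19 (6 and 3 adjusted over the list alone, list adjusted p = 0.0602), among them the alarmin Il33 (1.55) and the T cell attractant Cxcl9 (1.42). LXR targets had 5 and 2 of 14 (8 and 3 adjusted over the list alone, list adjusted p = 0.106), with Mertk at −1.01, and fatty acid oxidation and PPAR target genes 5 and 2 of 27 (6 and 4 adjusted over the list alone, 0.226), with the lipase inhibitor Angptl4 at 2.94 and the fatty acid transporter Cd36 at 1.06. Cholesterol synthesis had 0 higher and 1 lower of 15 in both counts (0.346), the feedback regulator Insig1 (−1.16). TGF-beta response (1 and 0 of 19, 0.489), ER stress (5 and 3 of 22, 0.546) and MHC class I genes (1 and 0 of 13, 0.747) did not pass, with 1 and 0, 5 and 3, and 0 and 0 adjusted over the list alone.

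Hepatocyte transcripts fell in endothelial-like cells, with 24 lower and 1 higher of 41 (28 and 2 adjusted over the list alone, list adjusted p = 4.6e-12, adjusted p = 0.181 with an estimated correlation), and neutrophil transcripts were higher, 2 of 3 (list adjusted p = 0.0399, adjusted p = 0.181 with an estimated correlation). The neutrophil call ended without Western diet library B (0.111), chow library C (0.0964) or chow library E (0.0536), with a range over alternatives of 1.8e-04 to 0.448. Dissociation stress (2 higher and 9 lower of 31, list adjusted p = 0.0602), erythroid (1 and 0 of 5, 0.346), immunoglobulin (0 and 0 of 4, 0.489), cell cycle (2 and 1 of 18, 0.588) and mitochondrial genes (0 and 0 of 13, 0.346) did not pass. The number of genes called was 1246 on day 1 alone and 495 without the day term, where Cxcl9, Lyve1 and Kitl lost their calls. Day 2 held 1 Western diet library of this class and was not tested alone.

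Cholangiocyte-like cells, which line the bile ducts, carried more transcripts of adhesion molecules and ductular reaction genes with the Western diet, and fewer of TGF-beta response and cholesterol synthesis genes. The last 3 lists lost their calls with an estimated correlation (0.116, 0.137 and 0.0698). Vcam1, an adhesion molecule for leukocytes, averaged 104.3 CPM ± 27.5 against 18.8 ± 6.37, and the matrix protease Mmp7 465.5 ± 120 against 143 ± 88.0 (SD, n = 6 per group). Id1, a target of BMP and TGF-beta signalling, averaged 323 ± 163 against 1169 ± 247. Of 5744 genes tested, 123 were higher and 88 lower, in libraries with 28 to 841 such cells and 99287 to 4008187 UMIs. On day 1 a cluster led by Ppp1r1b, Mmp7 and Spp1 held most cells of both groups (90.9% with the Western diet and 71.4% with chow). On day 2 a cluster led by Tstd1 and Epcam held 83.2% of Western diet cells, and one led by Ankrd1 and Sox9 held 76.5% of chow cells. Western diet library F gave 754 of the 829 Western diet cells of the Tstd1 cluster, and chow library F 248 of the 309 chow cells of the Ankrd1 cluster.

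Chemokine and cytokine genes, a list that also holds adhesion molecules, rose in cholangiocyte-like cells, 3 of 7 with 0 lower (4 and 0 adjusted over the list alone, list adjusted p = 3.6e-10, adjusted p = 0.00823 with an estimated correlation). Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) had a log2 fold change of 2.22 ± 0.19 (SE) with an adjusted p of 1.1e-06, and mean differences of 99.4 CPM on day 1 and 57.8 on day 2. The chemokine Cxcl16 had 2.19 and the adhesion molecule Icam1 1.42. Ductular reaction genes, expressed by proliferating duct cells of injured liver, rose in 6 of 23 with 0 lower (10 and 0 adjusted over the list alone, list adjusted p = 4.8e-07, adjusted p = 0.116 with an estimated correlation), with Mmp7 at 1.74 ± 0.23, osteopontin (Spp1) at 0.70 and the hyaluronan receptor Cd44 (at 2.84% of its highest class) at 1.89. Cholesterol synthesis genes fell in 6 of 17 with 0 higher (11 and 1 adjusted over the list alone, list adjusted p = 1.9e-09, adjusted p = 0.0698 with an estimated correlation). They included the squalene synthase Fdft1 (−0.84), the sterol oxidase Msmo1 (−0.99) and Insig1 (−0.94). TGF-beta response genes fell in 4 of 15 with 0 higher (6 and 1 adjusted over the list alone, list adjusted p = 0.0012, adjusted p = 0.137 with an estimated correlation): Id1 (−1.88 ± 0.26, adjusted p = 1.6e-04), Id3 (−1.73), the inhibitory Smad7 (−1.16) and Id2. The largest changes under the naming rule also included Basp1 (3.43), Pdlim4 (2.999), the tight junction gene Cldn2 (1.98) and the plasma protein genes Itih4 (2.96) and Vtn (1.75) upward. Itih4 and Vtn differed by 179 and 782 CPM on day 1 and by 45.1 and 176 on day 2. Hepatocyte transcripts as a list rose beside them but were lower on day 2 alone. The hepcidin gene Hamp2 (−2.98), the Wnt antagonist Sfrp5 (−2.01) and the transcription factor Atoh8 (−1.71) were among the largest decreases under that rule.

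MHC class II genes in cholangiocyte-like cells had 1 higher of 5, Cd74 (1.61, at 1.03% of its highest class), or 4 adjusted over the list alone (list adjusted p = 3.8e-05, adjusted p = 0.116 with an estimated correlation). Interferon response genes had 1 higher of 17, Bst2, or 2 adjusted over the list alone (list adjusted p = 0.00891, adjusted p = 0.291 with an estimated correlation). On day 2 alone the direction of that list turned over (adjusted p = 0.2, range over alternatives 8.2e-04 to 0.291). LXR targets had 1 higher, the cholesterol exporter Abca1 (1.21), and 1 lower, Apoe, of 10, or 3 and 1 adjusted over the list alone (list adjusted p = 0.0384, adjusted p = 0.116 with an estimated correlation). With thinned libraries the direction turned over (0.1876). The LXR call ended without Western diet library C (0.522), D (0.40) or F (0.0912) or chow library E (0.0822) or F (0.0528), with a range over alternatives of 0.0047 to 0.708. Biliary identity genes had 1 higher and 1 lower of 21 (2 and 5 adjusted over the list alone, 0.569), fatty acid oxidation and PPAR targets 0 and 1 of 25 in both counts (0.448), MHC class I 0 and 0 of 11 in both counts (0.569, median −0.06 with a test direction upward) and ER stress 0 and 0 of 18 (2 and 1 adjusted over the list alone, 0.569, median 0.02 and mean −0.02). Among technical lists, hepatocyte transcripts rose, 13 of 31 with 0 lower (16 and 0 adjusted over the list alone, list adjusted p = 1.2e-22, adjusted p = 0.116 with an estimated correlation), but were called lower on day 2 alone (adjusted p = 0.0153, range over alternatives 4.8e-67 to 0.450). Dissociation stress (2 higher and 3 lower of 28, 0.0579), cell cycle (1 and 0 of 9, 0.0624) and mitochondrial genes (0 and 1 of 12, 0.465) did not pass. The number of genes called was 437 among 4214 tested on day 1 alone, 218 on day 2 alone and 58 without the day term, where Smad7, Spp1, Cd44 and Insig1 lost their calls. Cd74, Fdft1 and Msmo1 lost theirs on day 2 alone, and Cd44 with limma-trend.

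**Figure D3:**
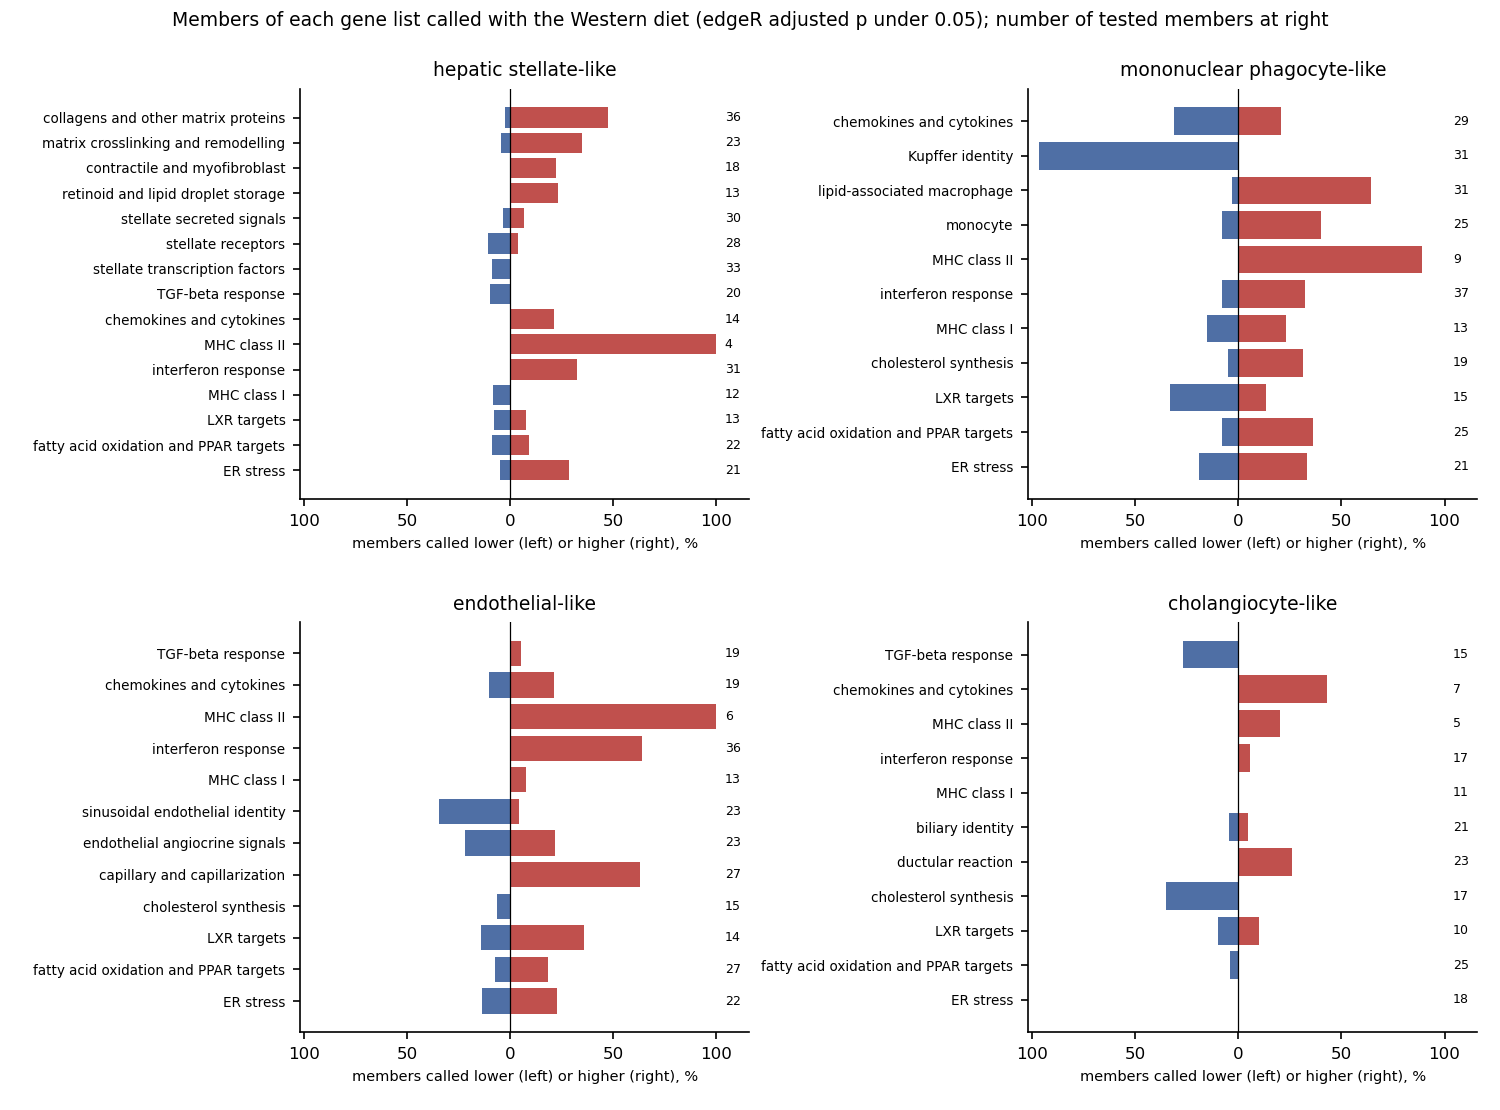
Percent of the measured members of each gene list called lower (left, blue) or higher (right, red) with the Western diet in 4 classes, with the number of measured members at the right. Kupffer identity genes were lower in 30 of 31 members in mononuclear phagocyte-like cells.

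In T cell-like cells, 1 of 761 genes tested was called, Apoe, a lipid carrier made mainly by macrophages and hepatocytes (log2 fold change 1.48 ± 0.25, adjusted p = 0.0296). It averaged 1809 CPM against 587, where mononuclear phagocyte-like cells averaged 53842 and 19626. It was chosen after its value was seen. The test covered 6 Western diet and 4 chow libraries with 10 to 623 such cells and 14889 to 3099539 UMIs, 46 genes had an unadjusted p under 0.05, DESeq2 called 2, limma-trend 0, day 1 alone 8 and day 2 alone 30. No gene was called without Western diet library C or F or chow library B or E, and 2 were called without Western diet library E or chow library D. Interferon response (0 of 4 called, list adjusted p = 0.335), MHC class I (0 of 9, 0.613), effector (0 of 15, 0.613) and residency and exhaustion genes (0 of 6 called, 1 higher adjusted over the list alone, 0.977, median −0.16 and mean 0.18) did not pass. The first 3 had 0 adjusted over the list alone. Dissociation stress (0 of 9, median 0.01 and mean −0.03), cell cycle (0 of 8, median −0.06 with a test direction upward) and mitochondrial genes (0 of 10) each had a list adjusted p of 0.613. The naive T cell list had fewer than 3 measured members. On day 2 alone the residency and exhaustion, MHC class I, dissociation stress and cell cycle lists turned direction.

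Hepatocyte-like cells of the Western diet carried more transcripts of Saa2 and Saa1 and fewer of Mup7 and Mup12. The acute-phase serum amyloid genes Saa2 and Saa1 had log2 fold changes of 5.24 ± 0.67 and 4.15 ± 0.58, at 6044 CPM ± 9624 and 5647 ± 8044 against 106 ± 112 and 183 ± 122 (SD, n = 6 per group). With shared barcodes removed the fold changes were 7.98 and 5.08 (adjusted p = 0.00356 and 0.00514), and over all alternatives they ranged from 4.21 to 7.98 and 3.02 to 5.98 (adjusted p up to 0.0391 and 0.0223). Most of the difference in level came from day 2, with mean differences of 276 and 647 CPM on day 1 and 17262 and 15098 CPM on day 2. Tceal8 had 3.13. Mup7 (−4.45 ± 0.55) and Mup12 (−4.21 ± 0.44), urinary pheromone carriers, and the fatty acid hydroxylase Cyp4a14 (−3.43 ± 0.61) were lower. Of 2200 genes, 72 were higher and 80 lower, in libraries with 17 to 2110 such cells. The number called was 57 without Western diet library E, 60 without Western diet library F, 90 without chow library A and 87 without chow library B. It was 34 on day 1 alone, 24 on day 2 alone, where Mup7 and Mup12 lost their calls, 355 with DESeq2 and 62 with limma-trend. Hepatocyte transcripts in this class fell as a list (2 higher and 3 lower of 43, 3 and 13 adjusted over the list alone), as did mitochondrial genes (0 of 11), both with a list adjusted p of 0.00265 and an adjusted p of 0.424 with an estimated correlation, and dissociation stress genes did not pass (0.595). On day 2 alone the first 2 lists turned direction (adjusted p = 0.541 and 0.103, ranges over alternatives 6.3e-05 to 0.541 and 1.3e-04 to 0.424). The mitochondrial list also turned with at least 1000 UMIs per cell and at Leiden resolution 2. On day 1 a cluster led by Mup7, Mup12 and Mup11 was the largest in both groups (40.5% with the Western diet and 83.1% with chow). On day 2 a cluster led by Orm2, Saa2 and Saa1 held 48.4% of Western diet cells, and one with Apob and Mup7 among its leading genes held 69.3% of chow cells, 1826 of its 1839 chow cells coming from chow library E. This class is a target of the antibody removal.

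B cell-like cells had 24 genes higher and 30 lower of 2612, in 5 Western diet and 3 chow libraries with 11 to 255 cells. The largest increases under the naming rule were in AC168977.1, on an unplaced contig (3.53 ± 0.50), the fatty acid carrier Fabp5 (2.49 ± 0.59) and the Fc receptor-like gene Fcrl5 (2.04 ± 0.39). The chromatin organiser Satb1 (−1.64 ± 0.34), Neurl3 (−1.58 ± 0.26) and Dmxl1 (−1.55 ± 0.34) were lower. With DESeq2 size factors the split was 18 higher and 38 lower. The number called was 93 without Western diet library A, 0 without Western diet library E or F, 14 without chow library E and 149 without chow library F, and 61 on day 2 alone. DESeq2 called 48, and limma-trend and the fit without the day term each called 0, where edgeR had 389 genes with an unadjusted p under 0.05. The call of AC168977.1 ended without Western diet library E (adjusted p = 0.0577) or F (0.0595), with a range over alternatives of 1.3e-14 to 0.225, and also with limma-trend and without the day term. That of Fabp5 ended in 7 of 14 alternatives: without chow library B (0.0614), with DESeq2, limma-trend, no day term, day 2 alone, at least 1000 UMIs or shared barcodes removed (0.0744), with a range of 1.4e-05 to 0.571. Hepatocyte transcripts fell (3 lower and 1 higher of 10, 6 and 1 adjusted over the list alone, list adjusted p = 3.7e-05, adjusted p = 0.191 with an estimated correlation), except without Western diet library E (0.124) or chow library F (0.703), with no doublet removal and with fry (0.0775), with a range over alternatives of 5.7e-08 to 0.703. Immunoglobulin transcripts rose as a list (1 higher and 1 lower of 8, 3 and 1 adjusted over the list alone, list adjusted p = 0.0320, adjusted p = 0.191 with an estimated correlation). Their call ended in most alternatives, among them without Western diet library D (0.0833), E (0.341) or F (0.171) or chow library B (0.119), E (0.440) or F (0.445), with a range over alternatives of 0.0193 to 0.5999. Dissociation stress (0.131), cell cycle (0.921) and mitochondrial genes (0.363) did not pass.

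In mesothelial-like cells, which cover the liver surface, edgeR called 0 of 961 genes in 6 Western diet and 3 chow libraries with 12 to 73 cells, 59 had an unadjusted p under 0.05, DESeq2 called 3 and limma-trend 1. On day 1 alone 13 were called. Omitting 1 library gave 2 without Western diet library A, 3 without B, 1 without C, 2 without D, 2 without E, and 1 without chow library C or D. Mitochondrial genes rose as a list with 0 of 10 called (list adjusted p = 8.5e-05, adjusted p = 0.294 with an estimated correlation), except without chow library C (0.181) and with fry (0.152, range over alternatives 7.8e-06 to 0.294). Dissociation stress (0.143) and cell cycle genes (0.714) did not pass.

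The diet effect differed between isolation days for 262 of 9452 genes in mononuclear phagocyte-like cells and 150 of 5744 in cholangiocyte-like cells by edgeR's interaction test. The effect was smaller on day 2 for the macrophage genes Gpnmb, Cd63, Plin2 and Plac8 and for Vtn and Cd74 in cholangiocyte-like cells. In stellate-like cells it differed for 12 of 6692 genes, among them the circadian factor Dbp (6.56), the glucocorticoid-induced genes Fkbp5 (2.76), Klf9 (2.12) and Sgk1 (1.85), and Col4a2 (−1.66), as the log2 effect on day 2 minus that on day 1. In endothelial-like cells it differed for 1 of 10042 genes, Gt(ROSA)26Sor. In T cell-like cells edgeR called 0 of 761, with 120 at an unadjusted p under 0.05 and 46 called by DESeq2. DESeq2 called more genes in the other classes too. Day 2 held 2 libraries per group (1 Western diet library of endothelial-like cells).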

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

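The tests of the Kupffer-led cluster and of shared barcodes were chosen after the results were seen. The tests of MHC class II genes against immune cell markers were written before.

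Single libraries stood apart in 30 of 274 groups of samples. Chow library F had 6, chow library E 5 and Western diet library F 4. Groups pooled both days and each marked share was on day 2, so a chance rate of 1 in 20 does not hold. Some gene marks were at 0 CPM. The measure is the gap to the nearest library of the group divided by the group's range. Chow library F held the highest chow shares of B cell-like cells (gap 0.864 of the range, 6.33% of named cells against 1.03% in the nearest library), NK and innate lymphoid-like cells (0.83, 1.77% against 0.303%), T cell-like cells (0.667, 10.2% against 3.57%), basophil and mast-like cells (0.882, 1.30% against 0.153%), neutrophil-like cells (0.794, 9.83% against 2.03%) and plasmacytoid dendritic-like cells (0.782, 0.442% against 0.096%). Chow library E held the highest chow shares of hepatocyte-like cells (0.777, 63.9% against 15.03%) and vascular smooth muscle-like cells (0.658, 0.242% against 0.083%). Western diet library F held the most cholangiocyte-like (0.654, 8.93% against 4.40%) and fibroblast-like cells (0.886, 5.96% against 0.763%) of its group, and Western diet library E the most erythroid-like (0.930, 12.4% against 0.86%) and mesothelial-like cells (0.707, 1.53% against 0.810%).

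Among named genes, read as log2 CPM, macrophage genes set apart Western diet library F for Marco (highest, 0.703), chow library E for Timd4 (highest, 0.666) and Western diet library A for H2-Eb1 (highest, 0.753). In stellate-like cells they were Western diet library D and chow library D for Osmr (lowest, 0.910 and 0.672), chow library E for Hand2 (highest, 0.673), and chow library D for H2-Ab1 (lowest, 0.748) and Scd1 (lowest, 0.632). In cholangiocyte-like cells they were chow library A for Itih4 (lowest, 0.869) and Cxcl16 (lowest, 0.647), chow library B for Id1 (lowest, 0.850) and chow library E for Cd74 (highest, 0.902). In endothelial-like cells they were Western diet library B for Ackr1 (lowest, 0.738) and Western diet library F for H2-Ab1 (lowest, 0.759). In hepatocyte-like cells they were chow library B for Tceal8 (lowest, 0.805) and Western diet library B for Mup12 (lowest, 0.684) and Cyp4a14 (lowest, 0.762), and in B cell-like cells Western diet library A for AC168977.1 (highest, 0.741).

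The diet effect of 7 named genes differed between isolation days in edgeR's interaction test. In mononuclear phagocyte-like cells the log2 effect on day 2 minus that on day 1 was −2.69 for Gpnmb (adjusted p = 0.00985), −1.53 for Plac8 (0.0280), −1.33 for Cd63 (0.0466) and −0.91 for Plin2 (0.0227). In cholangiocyte-like cells it was −2.21 for Cd74 (0.0154), −1.47 for Vtn (0.0444) and 1.33 for Msmo1 (0.0213).

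Cells left unnamed held 4 clusters with leading genes of other kinds, in percent of retained cells (SD, n = 6 per group). A cluster led by the neutrophil granule genes Ctsg, Elane and Mpo made up 0.440% ± 0.62 with the Western diet and 0.387% ± 0.614 with chow (exact permutation p = 0.571). Clusters led by the division genes Pimreg and Iqgap3 and by Cenpe, Cenpf and Mki67 made up 0.230% ± 0.23 against 0.031% ± 0.035 (exact permutation p = 0.0143, not adjusted) and 0.079% ± 0.128 against 0.072% ± 0.116 (exact permutation p = 0.833). A cluster led by Prg4, Alox15 and Serpinb2, genes of large peritoneal macrophages, made up 0.164% ± 0.165 against 0.048% ± 0.085 (exact permutation p = 0.171). It held 41 of 157 cells in clusters with these leading genes, and the others were counted as mononuclear phagocyte-like. Together they made up 0.552% ± 0.48 against 0.267% ± 0.128 (exact permutation p = 0.257).

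MHC class II genes, which macrophages and dendritic cells express far more highly, rose in endothelial-like and stellate-like cells. RNA from immune cells, free in the suspension or from doublets, would raise immune cell markers in step with them. Relative to 36 such markers, the MHC class II ratio to the other cells differed by 0.351 in endothelial-like cells (−0.819 ± 0.45, SD, n = 5, against −1.17 ± 0.95, SD, n = 6, exact permutation p = 0.281), and relative to 12 markers it differed by −0.223 in stellate-like cells (−0.725 ± 0.32, SD, n = 4, against −0.503 ± 0.615, SD, n = 6, exact permutation p = 0.511). Immune cell RNA may therefore account for both rises, although the median log2 fold change in endothelial-like cells was 2.88 for MHC class II genes and 1.33 for the markers. An effect of the diet on these cells stays open and was not tested apart from it.

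Kupffer identity genes fell in mononuclear phagocyte-like cells, whose Kupffer-led cluster held 55.0% of the class with chow and 20.7% with the Western diet (85.5% against 22.1% on day 1 and 21.8% against 18.99% on day 2). A smaller cluster led by Marco, Timd4, Kcna2 and C6, seen on day 2 alone, held 157 of 862 chow and 65 of 3043 Western diet cells there. With both clusters the day 2 shares were 40.0% against 21.1%. A lower share of the first cluster alone would leave its genes level within it, but 15 of 30 were lower inside it, Cd163 by a log2 fold change of −4.33, Marco −4.44 and Timd4 −1.69, while Folr2 (0.86) and Cd5l (0.46) were higher. Clec4f (0.20, adjusted p = 0.298) and Vsig4 (0.05, adjusted p = 0.784) were not called. With barcodes found in several libraries of a day removed, 29 of 30 were still lower. A mixture within the cluster of resident Kupffer cells and macrophages of another origin may remain, and the cluster was itself defined with such genes. A loss of these transcripts from resident cells with the diet stays open as a biological explanation and was not tested.

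Barcodes on day 2 recurred between libraries, in 575 to 1455 copies per pair against 9 to 85 on day 1 and 0 to 2 between days, and 3724 of 19363 retained day 2 cells carried one (19.23%, against 3.19% of 21543 on day 1). In chow library E 269 of 313 mononuclear phagocyte-like and 134 of 159 conventional dendritic-like cells were such copies, so these day 2 shares are uncertain. Chance gave a class agreement of at most 19.81% over the day 2 pairs, and the lowest seen was 96.31%. Barcodes differed between days although the labels give 1 protocol, so the number of copies by chance on day 2 is uncertain. The median copy held 4.09% of the UMIs of the fullest library. This pools 2 kinds: where Western diet library F was the fullest, 884, 588 and 543 copies in chow E, chow F and Western diet E held medians of 32.4%, 27.4% and 27.5%, and the other pairs had medians of 1.01% to 7.8%. Small copies may be molecules of 1 cell counted in several libraries sequenced together, and the source of larger ones stays open. The design gives no biological explanation to test. Day 2 values could therefore be less independent than the number of libraries says, and with these barcodes removed 383 genes were called in stellate-like, 3876 in mononuclear phagocyte-like and 223 in cholangiocyte-like cells.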

How the results depend on the processing

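Removing shared barcodes, testing libraries with at least 5 stellate-like cells and testing the Kupffer-led cluster alone were chosen after the data were seen. Named genes kept their direction throughout: over 3089 comparisons of the 123 named genes with an alternative, 0 reversed and 73 lost their call, 25 of them with limma-trend, 23 without the day term and 11 on day 2 alone, and 81 genes kept their call in each alternative that gave a value. These counts favour the named genes, because 7 less stable ones were left out.

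No class share was called in the exact test. The number called was 1 over all arrangements, 2 without hepatocyte-like and endothelial-like cells in the denominator, 4 with at least 1000 UMIs, 2 at Leiden resolution 2, 2 with shared barcodes removed, 3 with edgeR on cell numbers and 0 to 5 leaving out 1 library.

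In stellate-like cells (330 genes), the count was 26 with limma-trend, 532 with no filter on low counts, 71 without the day term, 112 on day 1 alone, 41 with thinned libraries, where 290 genes were tested, and 153 to 409 leaving out 1 library. In mononuclear phagocyte-like cells (3835), it was 2257 without the day term, 1453 with thinned libraries and 1633 in the Kupffer-led cluster alone, which holds fewer cells. In endothelial-like cells (1603), it was 495 without the day term. In cholangiocyte-like cells (211), it was 690 with no filter, 58 without the day term, 437 on day 1 alone and 109 with thinned libraries. Leaving out 1 library gave 3275 to 3790, 1073 to 2353 and 169 to 237 in these 3 classes.

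In T cell-like cells (1 gene), the count was 2 with DESeq2, 0 with limma-trend, 191 with no filter, 0 without the day term, 0 with the letter as a block, 8 on day 1 alone, 30 on day 2 alone, 2 at up to 20% mitochondrial UMIs, 93 with at least 1000 UMIs, 0 with no doublet removal, 0 for genes at 10% or more of their highest class, 2 with shared barcodes removed and 0 to 2 leaving out 1 library, where edgeR had 46 genes at an unadjusted p under 0.05.

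In hepatocyte-like cells (152), the count was 355 with DESeq2, 62 with limma-trend, 820 with no filter, 56 without the day term, 92 with the letter as a block, 34 on day 1 alone, 24 on day 2 alone, 32 with thinned libraries and 57 to 185 leaving out 1 library. In B cell-like cells (54), it was 0 with limma-trend, 254 with no filter, 0 without the day term, 86 at up to 20% mitochondrial UMIs, 101 with at least 1000 UMIs, 126 for genes at 10% or more of their highest class, 3 with thinned libraries and 0 to 149 leaving out 1 library. In mesothelial-like cells (0 with edgeR, 59 at an unadjusted p under 0.05), it was 3 with DESeq2, 1 with limma-trend, 42 with no filter, 14 with the letter as a block, 13 on day 1 alone, 1 with no doublet removal, 1 with thinned libraries and 0 to 3 leaving out 1 library. Fewer genes or libraries explain part of the lower counts of thinned libraries and single days, and otherwise the cause was not tested.

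Of the lists, 37 were called, 58 with no filter and 6 with an estimated correlation. On day 2 alone the direction turned over for monocyte (adjusted p = 0.564) and interferon genes (0.00384) in mononuclear phagocyte-like cells, for interferon (0.2), MHC class I (0.0169) and hepatocyte transcripts (0.0153) in cholangiocyte-like cells, for residency and exhaustion (0.00267), MHC class I (0.0484), dissociation stress (0.0484) and cell cycle genes (1.48e-31) in T cell-like cells, and for hepatocyte transcripts (0.541) and mitochondrial genes (0.103) in hepatocyte-like cells. It also turned over for LXR targets in cholangiocyte-like cells with thinned libraries (0.1876), for residency and exhaustion in T cell-like cells with no filter (0.01875) and with at least 1000 UMIs (1.77e-04), for cell cycle genes there with at least 1000 UMIs (5.53e-08) and without chow library D (0.0416, range 0.0416 to 0.695 leaving out 1 library), and for mitochondrial genes in hepatocyte-like cells with at least 1000 UMIs (0.1335) and at resolution 2 (0.362). The cause was not tested. Leaving out 1 library kept 917 of 973 list results, with 28 gaining and 27 losing the call.

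For the diet effect by day, DESeq2 called 69 genes in stellate-like, 403 in mononuclear phagocyte-like, 17 in endothelial-like and 46 in T cell-like cells, and 14 were called in T cell-like cells with shared barcodes removed. The cause was not tested. With the letter as a block, 278 genes were called in stellate-like, 3271 in mononuclear phagocyte-like, 1952 in endothelial-like and 164 in cholangiocyte-like cells. Not run for too few libraries were mesothelial-like cells at resolution 2 and on day 2, endothelial-like cells on day 2 and B cell-like cells on day 1. The smallest libraries held 12928 UMIs in B cell-like, 14889 in T cell-like and 19048 in stellate-like cells.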

Other observations

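Genes of this part outside the named ones, and the splits within day, were chosen after values were seen. The splits over both days were planned.

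Within the Kupffer-led cluster of 2322 cells, lipid-associated macrophage genes were higher in 18 of 26 members with 0 lower (list adjusted p = 5.7e-10, adjusted p = 0.208 with an estimated correlation), with Cd63 at a log2 fold change of 2.92, Gpnmb at 2.31 and Trem2 at 2.01. Interferon response genes were higher in 15 of 25 with 0 lower (list adjusted p = 8.4e-07, adjusted p = 0.32 with an estimated correlation), and all 6 measured MHC class II genes were higher. Of 4306 genes in the cluster, 784 were higher and 849 lower, with 2081 called on day 1 alone and 2 among the 1910 genes testable on day 2 alone. Dissociation stress genes were lower there in 11 of 21 members with 2 higher (list adjusted p = 0.0377, adjusted p = 0.407 with an estimated correlation).

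Among the genes whose diet effect differed between days, Klf9 and Dbp were called in stellate-like cells and in other classes, and no gene list was tested for this effect. Klf9 differed by 2.32 in mononuclear phagocyte-like and by 1.87 in cholangiocyte-like cells, and Dbp by 2.55 in cholangiocyte-like cells (edgeR adjusted p = 0.00425, 0.0241 and 1.3e-04). The hour of dissection and handling of each animal was not given in the sources used here, so no explanation was tested.

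Stellate, macrophage, endothelial and cholangiocyte differences went with the real groups more than with other groupings of the same libraries. Of 100 splits in stellate-like cells, the real one called 330 genes and the highest other 184, in mononuclear phagocyte-like cells 3835 and 805, in endothelial-like cells 1603 and 1433, in cholangiocyte-like cells 211 and 10, and in hepatocyte-like cells 152 and 28. In each of these 5 classes 1 of the 100 splits, the real one, called as many genes. These splits also crossed isolation days, so some mixed diet with day. Among splits that kept the number of libraries per group on each day, the highest other called 184 genes in stellate-like (90 splits), 805 in mononuclear phagocyte-like, 20 in endothelial-like, 36 in cholangiocyte-like and 42 in hepatocyte-like cells (100 splits each). The real split alone called as many in each of these 5 classes. With 90 or 100 splits this makes chance unlikely but does not exclude it. In hepatocyte-like cells the count also fell to 57 without Western diet library E and to 60 without Western diet library F. In B cell-like cells 1 of 56 splits called as many, with 54 and 33, and 1 of 24 within day, the smallest share possible there, with a highest other of 19. Their calls fell to 0 without Western diet library E or F, so chance stays open. In T cell-like cells 11 of 100 splits called as many as the real 1 and the highest other called 5 (3 of 90 splits within day, highest other 1). In mesothelial-like cells the real split called 0, all 83 splits as many and the highest other 2 (all 45 splits within day, highest other 2). Chance stays open in both. The endothelial split calling 1433 genes put Western diet libraries A, C, D and F with chow library F, so it exchanged a day 1 library for a day 2 library.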
